A study of Mus musculus with 155 samples.

How the data were processed

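Messenger RNA of 155 sorted mouse brain cells was measured by SMART-Seq2, with 1 cell per sample. Per the submitters' processing notes, kallisto and limma were used with genome build GRCm38; their versions are not given in the sources used here. The deposited table is described by its name as estimated counts for 3422 genes. Its values behaved as a normalized signal: in the deposited table the 8 highest values were the same in all cells (relative tolerance 1e-06) and column totals ran from 5155900 to 5161090, as after quantile normalization. The 10 highest genes held a median of 75.5% of a cell's total. How the 3422 genes were selected is not given in the sources used here, and a gene outside them was not analysed here.

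Cells were grouped by the labels' population name. As no mouse is named for any cell, each population was 1 sample, and no p-value, standard error or count of changed genes was computed. Comparisons, gene lists, the rule for named genes, the axis and the co-detection measure were fixed before the data were examined. That plan assumed raw counts. As the values were not raw counts and depth could not be read from them, scaled sums of counts, Poisson intervals and thinning to a fixed count could not be used as written, and replacements were chosen after seeing the data: the level became the mean of log2(value + 1) with the SD between cells, and thinned detection became presence among the 500 highest genes of a cell, the largest number tried that left out at most 10% of any population. It left out 2 NB cells with fewer detected genes. A difference of levels understates the difference of low genes.

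Named genes were the 10 each way with the largest difference in the share of cells having the gene among their 500 highest, given a scaled signal of at least 20 (value divided by the column total, times 1000000) in the higher population, a log2 ratio of mean values (1 added) of at least 1 and a difference of levels of at least 1 in the same direction. Up to 4 members per list described and a fixed set of 15 genes were added, of which 9 were measured. Olig2, Mki67, Gpr17, Gfap and Aqp4 were not analysed here, and some genes that the rule names are not reported here. Egfr, Top2a and other members of small lists are named under the same rule. All 185 named genes were placed on GRCm38 with GENCODE vM21.

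For each list the median difference was taken over members with a scaled signal of at least 5 in either population, where at least 4 remained, and its percentile among 10000 random lists matched on expression in 10 bins describes these cells only. The random lists come from the same 3422 genes, so if these were selected for differing between the populations, the percentiles would be affected. The lists were neuroblast, oligodendrocyte progenitor, newly formed and mature oligodendrocyte, S phase, cholesterol synthesis, glycolysis, chromatin regulators, migration and guidance, glial and neuronal fate transcription factors, ribosomal protein and mitochondrial genes. Lists with few measured members were astrocyte and neural stem cell, transit amplifying progenitor, G2 and M phase, microglia, endothelial, mural, ependymal, mature neuron, immediate early response, interferon, Notch, BMP targets and the sex-linked check. For the axis, 100 genes each way were chosen on NB and O cells; Gad1, EGFP and TdTomato were left out, the transgenes by a choice added after seeing the data.

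Sets of alike cells were made after seeing the data, by average linkage on the correlation of log2(value + 1). Mean correlations of 0.5, 0.45, 0.4 and 0.35 were all viewed before 0.4 was kept; the closing section says which results moved between them. Doublets were not called, and no cell was removed from the levels. Shares have exact Clopper-Pearson 95% intervals, which treat cells as independent and cover counting error only.

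The level and list steps were tested on simulated data made from the 3422 genes of each comparison, with 200 genes shifted by 3. The median shift recovered upward was 3.11 for OligNBL against NBL, 3.08 for OligNBL against OL, 2.97 for NBL against NB, 2.99 for OL against O and 3.01 for O against NB. In each comparison 20 of 20 shifted lists lay above the 97.5th percentile. The simulation shuffled each gene across cells on its own, which removed the sets of alike cells and the correlation between genes. Shifted lists held shifted genes only. The test thus checks the computation and cannot show how percentiles behave for lists of correlated genes or for lists held to a minimum signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Alternatives covered the weighting of cells, the highest cells, early cell numbers, genes detected, the pseudocount, the minimum level, the number and choice of axis genes, and the definition of detection.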

Results

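Single cells were sorted from the subventricular zone, the neurogenic wall of the lateral ventricle, and the corpus callosum, the white matter tract above it, of mice aged 8 to 10 weeks, and their polyadenylated RNA was sequenced by SMART-Seq2, a full-length single-cell protocol. The cells fell into 5 populations. NB (37 cells, GFP reporter of Gad67) and O (29 cells, Tomato reporter of Olig2) came from healthy mice. NBL (27 cells, GFP), OL (22 cells, Tomato) and OligNBL (40 cells, both reporters) came from mice killed 6 days after an injection of LPC, a detergent-like lipid that strips myelin. NB and NBL share a GFP strain, O and OL share a Tomato strain, and OligNBL mice were a cross of both, so strain differs with the gate in every comparison between gates. The labels give 5 mice per condition and name no mouse for any cell, so each population was treated as 1 sample, no test between populations was made, and differences are described without a replicate check. The labels place the 40 OligNBL cells in demyelinated mice, whereas their titles and the deposited description of the cells carry the control mark; they are called OligNBL throughout and the labels' lesion state is used.

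The values, named estimated counts, had nearly equal distributions across cells, as after quantile normalization, so sequencing depth could not be read from them: column totals differed by 0.101% over all cells. A gene's level is given as the mean of log2(value + 1) over cells with the SD between cells, and its presence as the share of cells with the gene among their 500 highest genes, with an exact 95% binomial interval where an interval is given. These intervals cover counting error only. A median of 1114 genes was detected per NB cell, 1161 per NBL cell, 1397 per OligNBL cell, 950.5 per OL cell and 1187 per O cell.

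Cells with neighboring cell numbers were more alike within each population. Each title holds this cell number and, in brackets, another number that repeats between populations. The bracketed number is the one meant where a title number is named. Mean correlation was between 0.49 and 0.56 for cells numbered at most 4 apart and between 0.19 and 0.35 for cells at least 17 apart. Joining cells at a mean correlation of 0.4 gave 20 sets of alike cells, which followed the cells' numbering, and 149 cells lay in 21 parts of at least 3 cells of the same population, with 6 cells outside. In 4 of the 20 sets cells of more than 1 population were joined. Levels were often all or nothing between sets of the same population, so SDs are large, and since cells are not independent, binomial intervals over cells are too narrow. For each comparison the number of leading genes whose set means did not overlap between the populations is therefore given. These genes were picked on the same cells for the largest differences in presence, and the sets were made from the same values. Such counts are thus partly built in and are no replicate check, and the share over all genes was not computed.

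**Figure D1:**
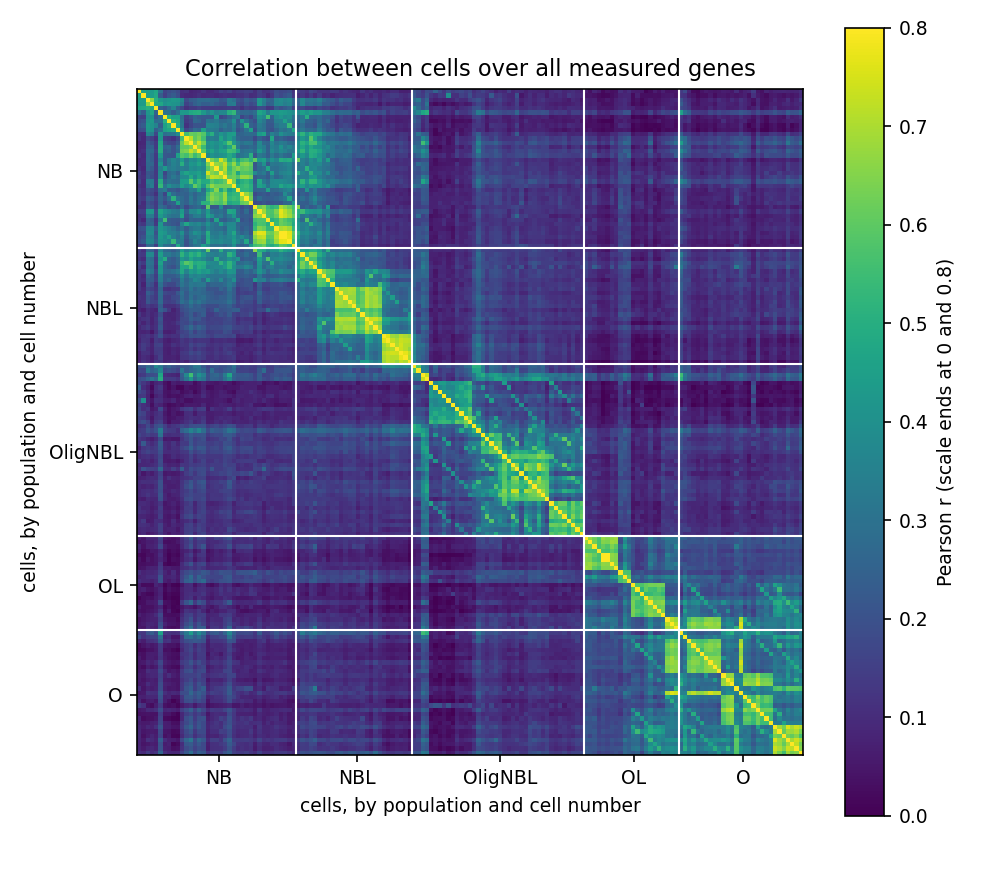
Pearson correlation over all genes of the table between each pair of cells, with cells on both axes ordered by population and then by cell number, white lines between populations, and a color scale from 0 to 0.8. Bright squares on the diagonal are runs of neighboring cell numbers, and a block of high correlation joins 3 OL cells to 9 O cells.

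**Figure D2:**
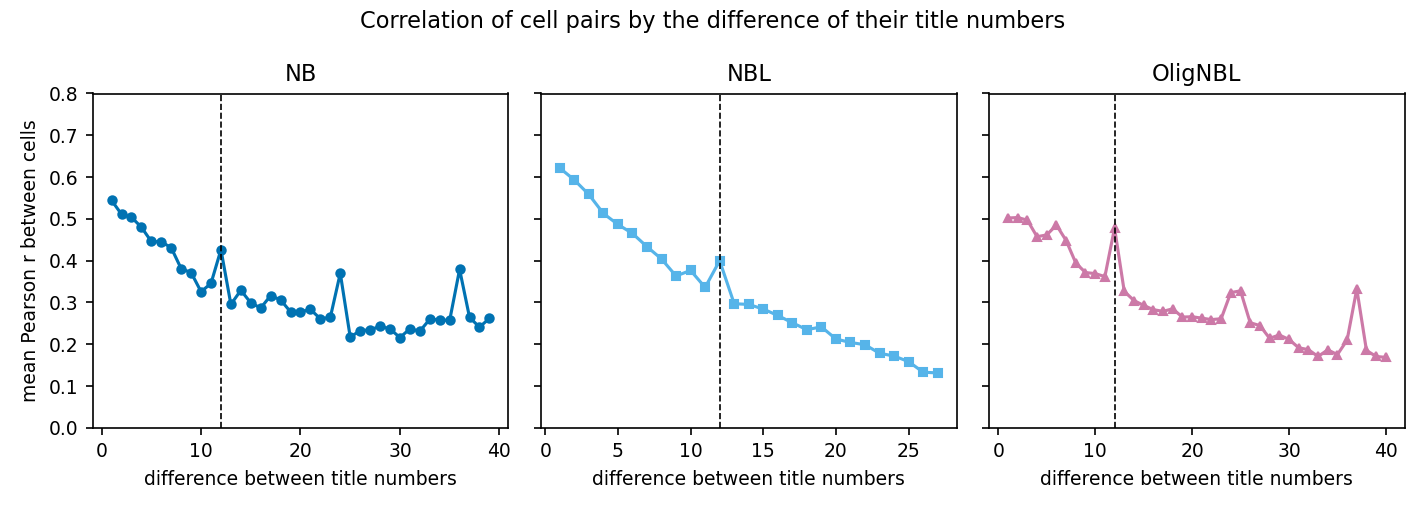
Mean Pearson correlation between cells of a population (vertical axis) by the difference between the bracketed numbers in their titles (horizontal axis) for NB, NBL and OligNBL, with a dashed line at 12. Correlation declines with the difference and stands higher at 12 than at 11 and 13, by 0.11 in NB, 0.08 in NBL and 0.13 in OligNBL.

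The reporters and their genes were examined first. EGFP transcript was among the 500 highest genes in 74.3% of NB cells (26 of 35), 25.9% of NBL cells (7 of 27), 30% of OligNBL cells (12 of 40), 9.09% of OL cells (2 of 22) and 3.45% of O cells (1 of 29). Gad1, which encodes the GABA-synthesizing enzyme Gad67, was there in 48.6% of NB cells, 7.41% of NBL, 55% of OligNBL, 9.09% of OL and 3.45% of O cells, an order unlike that of EGFP. TdTomato transcript did not separate the gates: it was among the 500 highest genes in 0 of 22 OL cells, which allows a share of up to 15.4%, in 1 of 29 O cells and in 1 of 40 OligNBL cells. The RNA of the Tomato reporter thus gave no check of the Olig2 gate, and Olig2 itself was not analysed here.

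The healthy populations, O against NB, from mice of different strains, differed by myelin genes on the O side and neuroblast genes on the NB side. The iron carrier Trf (GRCm38 chromosome 9, 103204001 to 103230444) had a level of 15.19 ± 2.92 in O (n = 29 cells) and 0.40 ± 1.20 in NB (n = 37 cells). The myelin enzyme Cnp was at 12.52 ± 2.67 against 0.23 ± 0.79, and the tight junction gene Cldn11 at 7.09 ± 4.29 against 0.00 ± 0.00. All 11 members of the mature oligodendrocyte list above the minimum were higher in O, with a median difference of 4.30 (2.69 with a pseudocount of 10). This had a percentile of 100 among 10000 random lists matched on expression. Random lists were not held to the minimum, so percentiles here and below can be too extreme. Of the 14 neuroblast genes, 12 were lower in O, with a median of -3.28 (-1.87 with a pseudocount of 10) and a percentile of 0.05. They included the transcription factor Sp8 (0.93 ± 1.16 in O against 7.63 ± 5.49 in NB), the microtubule regulator Stmn2 (0.73 ± 1.19 against 5.17 ± 4.77), the surface protein Cd24a (0.00 ± 0.00 against 4.37 ± 4.36) and Dcx, the microtubule protein of migrating neuroblasts (1.40 ± 1.57 against 5.46 ± 5.34).

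The leading genes higher in O were the actin-severing Gsn (29 of 29 O cells against 0 of 35 NB cells), the proteasome subunit Psmd6, Cnp, the prostaglandin synthase Ptgds, Fez1, Trf, Dapk1, Ndufa3, Abca2 and Klhl7. Those lower in O were the splicing factor Sf3b1 (2 of 29 against 34 of 35), Plppr3, Hmgn1, Pcif1, Tgoln1, Gabarapl1, Map4k3, Eif4g2, Napa and Ccnl2. The set means of all 20 leading genes lay apart between the populations. Ribosomal protein genes had a median of -1.38 (20 of 28 lower in O, percentile 0.03), chromatin regulators -1.77 (6 of 8 lower, percentile 1.97) and mitochondrially encoded genes 1.70 (5 of 6 higher, percentile 98.1). Newly formed oligodendrocyte genes (median 0.89), S phase genes (-0.25), migration genes (-0.99), glial fate factors (-0.53) and neuronal fate factors (-1.34) lay between the 13th and the 81st percentile. Set means lay apart for 10 of the 11 mature oligodendrocyte and 6 of the 14 neuroblast genes. With every measured member counted, the neuroblast median was -0.37, and the ribosomal median was -0.20 over members with a scaled signal of at least 50. The chromatin median was -0.91 in cells with at least 1000 genes detected, and with a pseudocount of 10 it was -1.12 and the mitochondrial median 0.88.

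OligNBL against OL compares the double reporter cells with the Tomato cells of demyelinated mice. Transcripts of myelin genes that were high in OL cells were low or not detected in OligNBL cells. Trf was at 0.39 ± 0.96 in OligNBL (n = 40) and 14.72 ± 4.58 in OL (n = 22), and Mbp, the myelin basic protein (chromosome 18, 82475146 to 82585637), at 0.04 ± 0.19 and 12.47 ± 4.79. Mbp was among the 500 highest genes in 0 of 40 OligNBL cells, which allows a share of up to 8.81%, and in 22 of 22 OL cells. All 13 mature oligodendrocyte genes were lower in OligNBL, with a median of -6.84 (-4.51 with a pseudocount of 10) and a percentile of 0. Neuroblast genes were higher in 12 of 15 cases (median 2.15, or 1.11 with a pseudocount of 10, percentile 99.8), led by the neuronal tubulin Tubb3 (8.81 ± 4.07 against 1.49 ± 2.57; chromosome 8, 123411424 to 123422015), Sox11 (5.99 ± 4.11 against 1.04 ± 1.65), Cd24a (3.65 ± 4.33 against 0.15 ± 0.50) and Nrep (4.14 ± 3.91 against 0.72 ± 1.81).

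Genes of oligodendrocyte progenitors went both ways in this comparison. The proteoglycan gene Cspg4 (4.08 ± 5.44 in OligNBL against 0.10 ± 0.46 in OL), the phosphatase gene Ptprz1 (3.52 ± 3.92 against 0.22 ± 0.77) and the growth factor receptor gene Pdgfra (4.05 ± 4.48 against 0.77 ± 1.35; chromosome 5, 75152292 to 75198215) were higher in OligNBL, whereas Sox10, a factor of the whole oligodendrocyte lineage, was lower (0.58 ± 1.76 against 4.47 ± 5.25). Of the 6 members 4 were higher, with a median of 3.08 and a percentile of 99.9; with every measured member the median was 0.34. S phase genes were lower in 5 of 6 cases (median -2.56, percentile 0.15), with Mcm5 among the 500 highest genes of 0 of 40 OligNBL and 9 of 22 OL cells, 8 of them in a single set of 8 cells; set means lay apart for 1 of the 6 genes. The S phase median was -1.51 with a pseudocount of 10 and -4.50 in cells with at least 1000 genes detected. The latter setting kept 9 of 22 OL cells, and only that single set had a median above 1000 genes among OL sets. Migration genes (7 of 8 higher, median 2.22), neuronal fate factors (5 of 7, median 2.15) and glycolytic genes (3 of 5, median 3.98, with Eno1, Hk1 and Pkm higher and Aldoa lower) had percentiles of 98.9, 97.9 and 100.0; with a pseudocount of 10 the first 2 medians were 1.17 and 0.90, and with every member the third was 1.95. Ribosomal protein genes had a median of 0.99 (31 of 42 higher, percentile 99.9; 0.49 with a pseudocount of 10), and chromatin regulators (1.17), glial fate factors (-0.20) and mitochondrial genes (-0.28) lay between the 24th and the 93rd percentile.

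The leading genes higher in OligNBL were Fxyd6, the RNA helicase Ddx5 (40 of 40 cells against 3 of 22), the semaphorin receptor Plxna2, Nono, the transcription factor Nfib (40 of 40 against 4 of 22), Dnajc7, Eva1c, Actg1, Tubb3 and Atat1. Those lower included Mbp, Trf, the serine synthesis enzyme Phgdh, the glycine transporter Slc6a9, Ptgds, Cldn11, Fez1, Tubb4a and Cryab. Set means lay apart for 18 of the 20 leading genes. The mice differed in strain as well as in gate.

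OligNBL against NBL compares double reporter with GFP cells, both from demyelinated mice, and asks how a cell with both reporters differs from a neuroblast of the same condition. The mice also differed in strain. Progenitor genes of the oligodendrocyte lineage went both ways. Cspg4 was at 4.08 ± 5.44 (n = 40) against 0.11 ± 0.52 in NBL (n = 27), Ptprz1 at 3.52 ± 3.92 against 0.45 ± 1.34, and Lhfpl3 at 2.88 ± 3.48 against 0.44 ± 1.37. Pdgfra was at 4.05 ± 4.48 against 2.75 ± 3.94, a difference of 1.30 that was smaller than either SD. Olig1 was at 0.90 ± 3.08 against 1.52 ± 2.45 and Sox10 at 0.58 ± 1.76 against 0.53 ± 1.34. The list had 5 of 7 members higher and a median of 1.30, inside the range of -1.21 to 1.53 that held 95% of random lists (percentile 96.1), and with every measured member the median was 0.058. Neuroblast genes were higher in 10 of 16 cases (median 0.81, percentile 95, also inside the range of random lists, -0.93 to 1.01), with Meis2 (4.15 ± 2.52 against 0.59 ± 1.48) and Tubb3 (8.81 ± 4.07 against 5.57 ± 4.72) higher and Elavl4 (0.83 ± 1.48 against 4.78 ± 5.77) and Nrep (4.14 ± 3.91 against 8.01 ± 5.18) lower. Mature oligodendrocyte genes had too few members above the minimum for a median, and Mbp was at 0.04 ± 0.19 against 0.13 ± 0.53.

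Other gene groups had medians outside the range of random lists. Ribosomal protein genes were higher in 32 of 37 cases (median 1.44, percentile 100), migration genes in 7 of 9 (median 1.71, percentile 97.9) and glycolytic genes in 3 of 4 (median 2.67, percentile 98.7). The glycolytic median was 0.58 with every measured member and 1.52 with a pseudocount of 10, which also gave 0.67 for ribosomal and 0.94 for migration genes. Cholesterol synthesis genes had a median of -1.95 and a percentile of 1.47, with Dhcr7 (2.17 ± 3.41 against 8.38 ± 4.55) lower and Insig1 and Srebf2 higher. This median was -0.34 in cells with at least 1000 genes detected and -0.85 with a pseudocount of 10. Chromatin regulators (-0.41), glial fate factors (-0.34), neuronal fate factors (0.13) and mitochondrial genes (0.45) lay between the 16th and the 77th percentile. The leading genes higher in OligNBL were 4833439L19Rik (34 of 40 against 0 of 27), Olfr1124, Plxna2, Nono, Eva1c, Fxyd6, Snrpb, Dnajc7, Rrp7a and Matr3. Those lower were the heterochromatin protein Cbx5 (0 of 40 against 25 of 27), the bromodomain gene Brd2, Clic4, Smarce1, Zfp119a, the cadherin Cdh2, Scg5, March7, Ptpn5 and Sec22b. Set means lay apart for 16 of the 20. OligNBL cells also had more genes detected, a median of 1397 against 1161.

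NBL against NB compares GFP cells of the same strain with and without demyelination. The largest differences in presence were mostly in genes outside the neuroblast list, with Nrep as the exception. The RNA-binding gene Celf3 was at 8.96 ± 4.78 in NBL (n = 27) against 0.69 ± 2.54 in NB (n = 37), Nfib (chromosome 4, 82290173 to 82705750) at 10.31 ± 5.59 against 1.74 ± 2.42, and the growth kinase Mtor at 7.75 ± 6.01 against 0.10 ± 0.62, whereas the glycolytic gene Gapdh was at 1.24 ± 1.99 against 8.01 ± 5.71 and the dendritic gene Map2 at 0.53 ± 0.91 against 6.23 ± 4.85. The set means of Celf3, Nfib, Mtor, Gapdh and Map2 all overlapped between the populations. Neuroblast genes had 10 of 15 members lower, a median of -0.69 and a percentile of 7.48: Sp8 (1.74 ± 1.39 against 7.63 ± 5.49) and Stmn2 (0.76 ± 1.51 against 5.17 ± 4.77) were lower, and Nrep (8.01 ± 5.18 against 0.67 ± 2.01) and Elavl4 (4.78 ± 5.77 against 0.15 ± 0.63) were higher. Dcx was at 5.14 ± 2.95 against 5.46 ± 5.34, with NB sets between 0.74 and 12.36, but was among the 500 highest genes in 23 of 27 NBL and 20 of 35 NB cells.

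Ribosomal protein genes were lower in 18 of 27 cases (median -0.65, percentile 0.52), and the median was -0.0049 with every measured member and -1.58 in cells with at least 1000 genes detected. Chromatin regulators (median 0.02), migration genes (1.18), glial fate factors (0.26), neuronal fate factors (-0.69) and mitochondrial genes (-0.25) lay between the 14th and the 92nd percentile. The other leading genes were Map7d1, Ptpn5, Scg5, Scaf11, Nrep, Rab14 and Zfp422, higher in NBL, and Gm7336, Ctxn1, Ccnl2, Lrrc8a, Nxf1, Dazap2, Eif4g2 and Itpr1, lower. Set means lay apart for 8 of the 20 leading genes, a number that depends on the correlation at which sets are joined (13 at 0.5, 10 at 0.35). These 8 were Map7d1, Ptpn5, Scg5, Nrep, Rab14 and Zfp422, higher in NBL, and Nxf1 and Dazap2, lower. In 2 sets 5 NBL cells were joined with 17 NB cells. In the set with 3 NBL and 6 NB cells, 13 of the 20 leading genes differed by at least 1 in the direction of the whole populations. The genes were picked on all cells, these included, so this agreement is partly built in. The share over all genes was not computed. Against that direction, Nfib was at 1.22 in NBL and 2.72 in NB, and Eif4g2 at 7.74 and 6.49. Mtor and Scaf11 were at 0 in both.

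OL against O compares Tomato cells of the same strain with and without demyelination. Mbp was at 12.47 ± 4.79 in OL (n = 22) and 3.00 ± 3.02 in O (n = 29), and among the 500 highest genes in 22 of 22 against 7 of 29 cells. The myelin genes Mal (6.84 ± 6.22 against 1.02 ± 1.69) and Mag (7.38 ± 5.51 against 4.18 ± 4.52) were also higher, and Ugt8a, an enzyme of myelin lipid synthesis, was lower (1.51 ± 2.02 against 4.27 ± 4.23). Of 14 mature oligodendrocyte genes 10 were higher, with a median of 1.24 and a percentile of 100.0; with sets weighted equally the median was 0.79. Inside the set that held cells of both populations, Mbp was at 4.81 in 3 OL cells and 3.79 in 9 O cells, a difference of 1.02 against 9.47 between the whole populations; these OL cells are in that set because their profiles resemble those of the O cells.

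S phase genes were higher in 5 of 6 cases (median 1.89, percentile 99.8), with Mcm5 in the 500 highest genes of 9 of 22 OL and 3 of 29 O cells and Cdc6 in 8 and 3. The receptor gene Egfr was there in 8 of 22 and 3 of 29. A single set of 8 OL cells held 8 of the 9 OL cells with Mcm5 and all 8 with Cdc6 or Egfr, and Cdc6 and Egfr lay below the O level in the other 3 of 4 OL sets. The S phase median was 1.25 with a pseudocount of 10, 1.31 with sets weighted equally and 3.74 in cells with at least 1000 genes detected. The last setting kept 9 of 22 OL cells. Among OL sets, only that set of 8 cells had a median above 1000 genes (1076.5). The value of 3.74 can thus rest on that set. Set means lay apart for 0 of the 6 S phase and 2 of the 14 mature oligodendrocyte genes. Ribosomal protein genes were higher in 20 of 26 cases (median 1.10, percentile 100; 0.23 with every measured member). Neuroblast genes had 3 of 5 higher (median 1.52, percentile 98.6), and this median was -0.01 when all members were counted. Newly formed oligodendrocyte genes (-0.01), chromatin regulators (-0.36), migration genes (-0.47), glial fate factors (0.34) and mitochondrial genes (-0.44) lay between the 17th and the 90th percentile. The other leading genes higher in OL were Nelfb, Nkain2, Fbxl5, Ikzf5, Got1, the DNA demethylase Tet2, Sphk2, Rplp0 and Hsp90ab1, and those lower were Psmd6, Dapk1, Arpc5, Klhl7, Ubap1, mt-Co1, Gm29216, Spg20, 2010111I01Rik and Ndufs4. Set means lay apart for 7 of the 10 higher and 0 of the 10 lower genes.

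**Figure D3:**
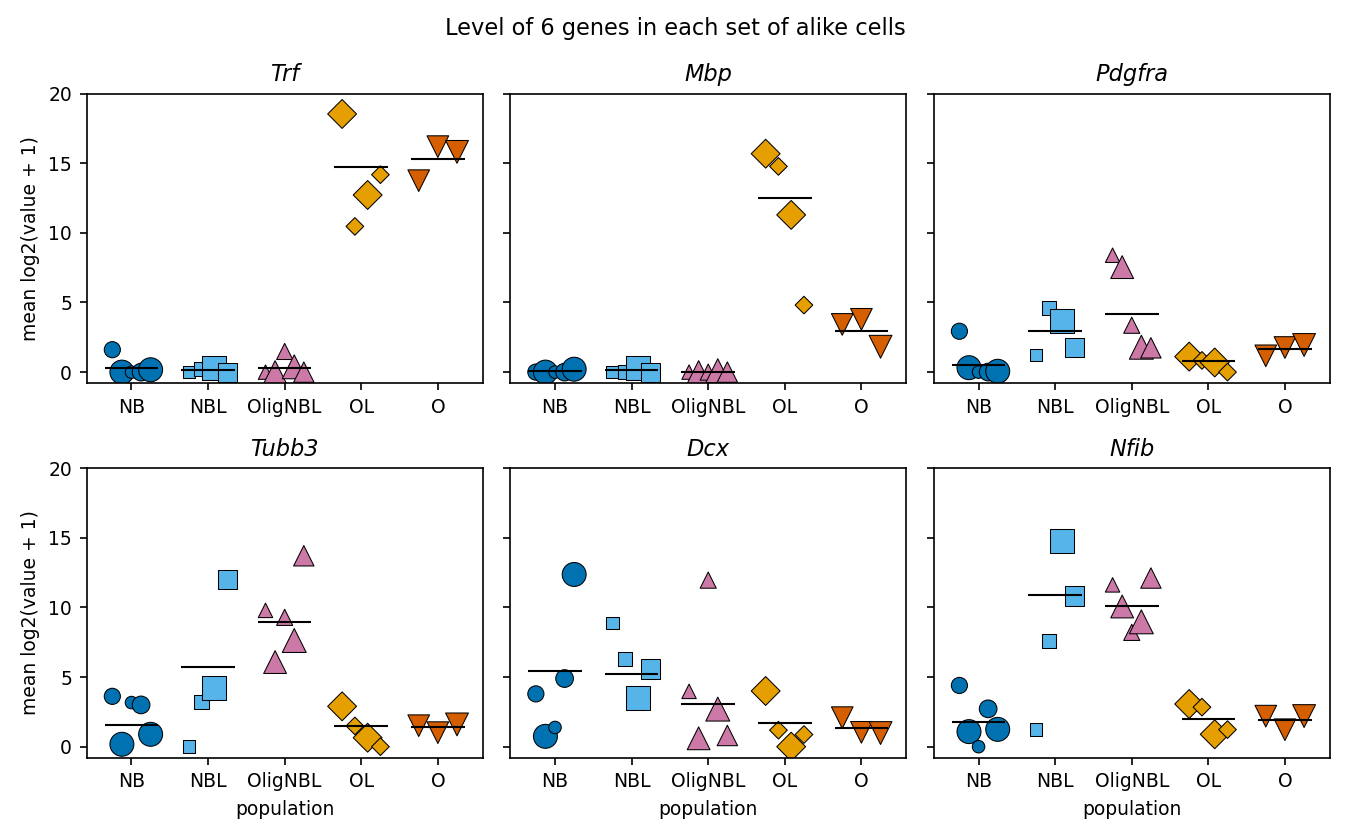
Mean log2(value + 1) of 6 genes in each set of alike cells with at least 3 cells of the population; point area grows with the number of cells, the horizontal line is the mean over the cells shown, and the horizontal axis names the population. Mbp was at 4.81 in the lowest OL set and at 3.79 in the highest O set, which are parts of the same shared set. Pdgfra differed widely between OligNBL sets.

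The position of each cell between NB and O was measured with 100 genes higher in O and 100 higher in NB. With the median NB cell at 0 and the median O cell at 1, the median was 0.42 in NBL (quartiles 0.21 and 0.46), 0.48 in OligNBL (0.44 and 0.50) and 0.71 in OL (0.66 and 0.77). All 40 OligNBL cells lay between 0.25 and 0.75, and 8 of them (20%, interval 9.05 to 35.6%) lay above 0.5, against 2 of 27 NBL and 22 of 22 OL cells. The highest OligNBL cell was at 0.54, and the share was 0% with 50 genes each way or in cells with at least 1000 genes detected, 2.5% with fixed lists and 8.33% without cells numbered 1 to 21. NBL sets ran from 0.0020, in the set shared with 6 NB cells, to 0.45. The middle position of OligNBL went with low values of both gene groups: the median cell had 0.56 for the O genes and 0.75 for the NB genes, in mean log2 of scaled signal plus 1, against 4.13 for O genes in O cells and 4.13 for NB genes in NB cells. The genes were chosen on the same NB and O cells, which raises the values of those populations; with genes chosen without the set of the scored cell, these became 2.42 and 2.49. For the opposite group, O genes in NB cells were at 0.09 and NB genes in O cells at 0.19, or 0.22 and 0.31 with genes so chosen. These lie below the OligNBL values. The genes were, however, chosen to be low in the opposite population, and leaving out the scored set removes this only in part. These values are therefore no background level for OligNBL cells. The median NBL cell had 0.39 for the O genes and 1.11 for the NB genes. On the neuroblast and oligodendrocyte lists fixed beforehand, the OligNBL median was -0.01, beside NB at 0, and NBL was at 0.07 and OL at 1.13.

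**Figure D4:**
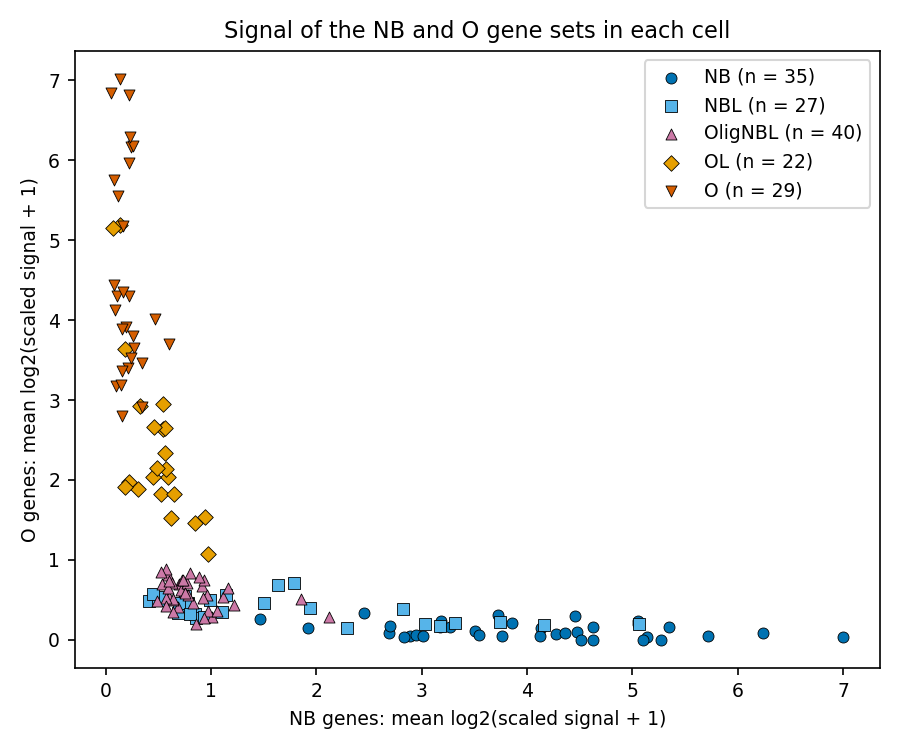
Mean log2 of scaled signal plus 1 over the 100 NB genes (horizontal axis) and the 100 O genes (vertical axis) for each cell, with genes outside a cell's 500 highest set to 0 and color and marker for the population. OligNBL cells lie near the origin, with medians of 0.75 and 0.56, while the NB and O cells on which the genes were chosen reach along the axes.

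Joint presence of both gene groups in a cell was measured as at least 3 neuroblast genes and at least 3 oligodendrocyte lineage genes among the 500 highest. This held for 40% of OligNBL cells (16 of 40, interval 24.9 to 56.7%), 29.6% of NBL (8 of 27, 13.8 to 50.2%), 31.8% of OL (7 of 22, 13.9 to 54.9%), 24.1% of O (7 of 29, 10.3 to 43.5%) and 14.3% of NB cells (5 of 35, 4.81 to 30.3%), so the OligNBL share lay within the intervals of NBL, OL and O. At least 3 neuroblast genes were present in 40 of 40 OligNBL, 27 of 27 NBL, 31 of 35 NB, 7 of 22 OL and 7 of 29 O cells. The joint share thus counts lineage genes alone in OligNBL and NBL. In OL and O, where all cells had at least 3 lineage genes, it counts neuroblast genes alone. The share depends on the definition: in OligNBL and NBL it was 5.00% and 7.41% with at least 5 genes of each side, 12.5% and 7.41% among the 300 highest genes, and 100% and 77.8% with any detected value. The lineage genes include Tcf7l2, which was among the 500 highest genes in 26 of 27 NBL, 21 of 35 NB, 10 of 40 OligNBL and 13 of 22 OL cells. It was thus not limited to the lineage here and counts toward the NBL share, and the share without it was not computed. At least 3 progenitor genes were present in 13 of 40 OligNBL, 3 of 27 NBL, 1 of 29 O, 0 of 35 NB and 0 of 22 OL cells. At least 3 mature oligodendrocyte genes were present in 0 of 40 OligNBL, 1 of 27 NBL, 1 of 35 NB, 22 of 22 OL and 29 of 29 O cells. Pdgfra together with at least 3 neuroblast genes was found in 42.5% of OligNBL cells (17 of 40, 27 to 59.1%), 25.9% of NBL (7 of 27, 11.1 to 46.3%), 8.57% of NB, 3.45% of O and 0 of 22 OL cells. As all OligNBL and NBL cells had the neuroblast genes, in these populations this is simply the share with Pdgfra among the 500 highest genes. Among cells with 1000 to 1400 genes detected the share was 22.2% in OligNBL (4 of 18) and 23.5% in NBL (4 of 17), but the NBL interval of 6.81 to 49.9% would also hold the full OligNBL share, so these cells are too few to show whether the excess remains at matched numbers of genes.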

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

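Except for the tests on genes detected, the tests in this part were chosen only after the results were seen, and so were the sets of alike cells and the number difference of 12, which was picked after all differences had been plotted; OL was given its own test of best matches, with counting error, after its value of 50% was seen.

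Reporter RNA appeared where the strain labels name no such transgene: TdTomato was detected in 48.1% of NBL cells (13 of 27) and 8.11% of NB cells (3 of 37), against 13.6% of OL (3 of 22), 17.2% of O (5 of 29) and 17.5% of OligNBL cells (7 of 40), which the labels do give the reporter, and EGFP was detected in 24.1% of O cells (7 of 29) and 9.09% of OL cells (2 of 22). The ribosomal protein list had a median of -0.65 in NBL against NB and 1.10 in OL against O, opposite signs whose difference was not tested; with every measured member these were -0.0049 and 0.23.

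Neighboring cell numbers had alike profiles in every population. The bracketed title numbers, which are not the cell numbers, were used for a step of 12, the row length of a 96-well plate. Mean correlation at a title number difference of 12 exceeded that at 11 and 13 by 0.108 over NB, NBL and OligNBL (0.11, 0.08 and 0.13), though by -0.01 in OL and 0.00 in O. At 24 the excess was 0.13 in NB, 0.00 in NBL, 0.03 in OligNBL and 0.13 in O, and at 36 it was 0.12 in NB and -0.05 in OligNBL. In OligNBL, correlation was also high at 25 (0.328, against 0.251 at 26) and at 37 (0.332, against 0.185 at 38). These differences serve as values beside 24 and 36, which lowers the excess there. Plate rows are thus not shown by all exact multiples, and a library batch or plate position stays open. The number of genes detected is argued against as the cause, since pairs matched within 10% kept 104% of the decline in correlation with cell number distance. The animal cannot be told apart from a batch, because no mouse is named for any cell: 3 OL cells correlated more with 9 O cells of their set than with other OL cells, by 0.37, but the set was joined on this correlation, so its outcome was built in. These OL cells had cell numbers 192 to 194, and the O cells 195 to 208. By contrast, 3 NBL cells numbered 58 to 61 were joined with 6 NB cells numbered 27 to 34. A further 2 NBL cells lay in a set of NB cells numbered 22 to 59. The joined cells come from different mice, healthy and demyelinated, but are few, and the cause was not tested. Populations still differed beyond the sets: with a cell's own set left out, at least 85.2% of NB, NBL, OligNBL and O cells matched their own population best, but 50% of OL cells did (11 of 22), which leaves OL against O undecided. The populations hold mostly separate runs of cell numbers, so a batch common to a population would give the same matches. These matches therefore cannot tell a difference of the population from a batch.

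For higher Mbp in OL than in O, library batch or plate position and the lesion cannot be told apart. Inside the set shared by both populations the difference was 10.8% of that between the populations, but on 3 OL cells that were joined to 9 O cells for resembling them, so a small difference there is partly built in. The lowest OL set lay 1.02 above the highest O set, but these are the OL and O cells of that shared set. This is therefore the same difference and no separate observation. The other OL sets hold no O cells.

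Pdgfra beside neuroblast genes was found in 17 of 40 OligNBL cells. By rows of 12 title numbers, which do not depend on expression, it was found in 8 of 8, 4 of 4, 2 of 6, 1 of 9, 1 of 11 and 1 of 2 cells. Rows with at least 3 cells differed by up to 90.9 percentage points (100%, interval 63.1 to 100%, against 9.09%, 0.23 to 41.3%), so batch or plate position could account for it. Genes detected cannot be told apart from the population: at 1000 to 1400 genes the share was 22.2% in OligNBL and 23.5% in NBL, whose interval of 6.81 to 49.9% would also have held the full share of 42.5%. A difference of the sorted population itself stays open.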

How the results depend on the processing

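The settings with at least 1000 genes, a pseudocount of 10, sets weighted equally, 300 highest genes, other set correlations and axis genes chosen without the scored set were added after the results were seen. Log2 ratios of mean values, which weigh the highest cells most, moved 248 of 370 gene differences by more than the SD between cells and 44 of 47 list medians by more than the SD of random lists; over all settings 259 of 2220 and 122 of 376 moved. A sign change was counted as a reversal only for a leading gene, a gene difference of at least 1 that also reached the SD between cells, or a list median outside the range of random lists: this gave 0 of 1146 gene differences and 1 of 176 list medians, the neuroblast list in OL against O (-0.0096 with every member). Leading genes were picked to have the same sign in the log2 ratio of mean values, so that setting could not reverse them. Among the smaller differences 83 of 1074 gene values and 38 of 200 list medians changed sign, so their directions are open. Of these, 10 gene values, all as log2 ratios, and 11 list medians, 5 as log2 ratios, moved by more than the SD (OL against O mt-Cytb -3.72, Sox10 -2.24; OligNBL against NBL Olig1 5.31, glial fate 2.94). Of 90 shares of single genes 35 moved, of 36 axis values 13 and of 25 shares with joint presence 14. With every member the neuroblast medians were also -0.37 in O against NB and 0.23 in OligNBL against NBL, and the progenitor median in OligNBL against NBL was 0.058; members with a scaled signal of at least 50 gave -1.66 for NBL against NB, 1.34 and 2.45 for OligNBL against NBL (neuroblast, progenitor). Log2 ratios gave neuroblast medians of -4.03 (NBL against NB), -8.81 (O against NB), 4.76 (OligNBL against NBL) and 6.99 (OligNBL against OL), a progenitor median of 5.31 (OligNBL against NBL) and mature oligodendrocyte medians of 11.15 (O against NB), 1.90 (OL against O) and -13.36 (OligNBL against OL). A pseudocount of 10 gave 2.69 and -1.87 in O against NB (mature, neuroblast) and -4.51 and 1.11 in OligNBL against OL. Cells with at least 1000 genes gave -1.50 (NBL against NB, neuroblast), 0.69 (OligNBL against NBL, progenitor) and -7.40 (OligNBL against OL, mature). That setting kept 21 NB, 22 NBL, 38 OligNBL, 9 OL and 21 O cells. Sets weighted equally gave -1.09 (NBL against NB, neuroblast) and 0.79 (OL against O, mature). Without cells numbered 1 to 21 the O against NB neuroblast median was -2.06, and without the 2 highest cells the OligNBL against OL mature median was -5.66. On the axis, the share above 0.5 was 0% in NBL with 50 genes, all values, fixed lists, at least 1000 genes and without cells 1 to 21; in OligNBL it was 0% with 50 genes and at least 1000 genes, 2.5% with fixed lists and 8.33% without cells 1 to 21. The median was 0.40 in OligNBL with 50 genes, and with fixed lists 0.068 in NBL, -0.013 in OligNBL and 1.13 in OL. Joint presence was most open to its definition: any detected value gave 70.3% of NB, 77.8% of NBL, 100% of OligNBL, 95.5% of OL and 82.8% of O cells; at least 5 markers of each side gave 7.41% of NBL, 5.00% of OligNBL, 0% of OL and 3.45% of O; the 300 highest genes gave 7.41% of NBL, 12.5% of OligNBL, 4.55% of OL and 0% of O; and at least 1000 genes gave 4.76% of NB. Leading genes with set means apart, at set correlations of 0.5, 0.45, 0.4 and 0.35, numbered 13, 8, 8 and 10 for NBL against NB, 20, 16, 16 and 16 for OligNBL against NBL, and 19, 18, 18 and 18 for OligNBL against OL, and were 7 for OL against O and 20 for O against NB at each; own-population matches were 81.5% in NBL and 91.9% in NB at 0.5, 100% in NB at 0.45, and 85.2% and 97.3% at 0.4; the set of 3 OL and 9 O cells was the same size at each. Apart from these constructions the cause of the moves was not tested. TMM and median-of-ratios scaling and detection at 5 counts were not run, since the values are no longer counts. As 0 cells reached 2000 genes, that setting gave no value. Leaving out cells with 3 markers of another cell type could not be done. The microglia, endothelial, mural and ependymal lists had 0, 1, 0 and 0 measured members, so no cell could reach 3. No paired analysis was possible because the numbers in the labels pair no cell of a population with a cell of another, and no test between populations was made; cells joined in a set are not pairs. Depth per cell is unknown, so a gene missing from a cell cannot be told from a gene not sampled.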

Other observations

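Some lists had too few measured members for a median, so their genes are given singly and say nothing of a group. Ifit1, an interferon-response gene, was at 3.13 ± 3.64 in OligNBL (n = 40 cells) against 0.08 ± 0.30 in NBL (n = 27 cells). The receptor gene Notch1 was at 4.97 ± 5.47 in NBL against 0.15 ± 0.60 in NB and 0.15 ± 0.83 in OligNBL, with 11 of its 12 NBL cells in a single set, and the Notch-modifying enzyme Mfng at 3.00 ± 2.91 in OligNBL against 0.42 ± 0.85 in NBL. The immediate early genes Junb and Nr4a1 were at 2.08 ± 3.73 and 2.91 ± 4.83 in NBL against 0.10 ± 0.61 and 0.01 ± 0.04 in NB, with 7 of the 8 and all 7 NBL cells that had them among the 500 highest genes in a single set, whereas Ier2, of the same list, was at 0.82 ± 1.58 against 1.75 ± 4.00. The BMP pathway gene Smad9 was at 0.46 ± 1.79 in OL against 3.26 ± 3.53 in O, and the BMP receptor gene Bmpr2 at 1.91 ± 2.30 in OligNBL against 0.55 ± 0.99 in NBL. No test was made of any of these.

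Of the G2 and M phase list, Top2a was among the 500 highest genes in 11 of 27 NBL cells, which were the 11 cells of a single set, and 0 of 35 NB cells, Ckap2l in 4 of 27 and 12 of 35, and Birc5 in 0 of 27 and 2 of 35. Egfr, the measured member of the transit amplifying list, was there in 8 of 22 OL cells, 3 of 29 O cells and 0 of 40 OligNBL cells, the OL cells being the 8 cells of a single set. Pecam1, an endothelial gene and the measured member of its list, was among the 500 highest genes in 32 of 35 NB, 27 of 27 NBL, 38 of 40 OligNBL, 21 of 22 OL and 29 of 29 O cells, so it did not mark a cell type here. Of the mature neuron list, Snap25 was there in 18 of 29 O cells against 0 of 35 NB cells, and Snhg11 in 20 of 29 and 21 of 35. The Y-linked gene Uty was detected in 14 of 37 NB, 8 of 27 NBL, 10 of 40 OligNBL, 6 of 22 OL and 11 of 29 O cells. The astrocyte and neural stem cell, microglia, mural and ependymal lists had 0 measured members, so cells of those types were not looked for here.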
